A study of Rattus norvegicus with 6 samples.

How the data were processed

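Gene expression was measured on 6 Affymetrix rat arrays of the Gene ST type, each hybridised with biotin-labelled RNA made from 6 µg of total RNA from cerebral arteries of male rats. Per the labels, 3 arrays held arteries taken 6 hours after subarachnoid haemorrhage (SAH), which bear the numbers 1, 4 and 5, and 3 held arteries of sham-operated rats, which bear the numbers 6, 7 and 8. The labels give no time after surgery for the sham arrays. No scan date or batch is given in the sources used here. The array numbers run with the groups, and the labels do not say whether they give an order of processing. The labels number the samples without saying that each came from another animal, so the p-values measure the spread between these samples.

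The deposited values are log2 expression values. Per the submitters' processing notes, the authors used Affymetrix Expression Console 1.1.2 and RMA, a method that corrects background, applies quantile normalization and summarises the probes of each probe set. The order and settings of these steps, and any genome build, are not given in the sources used here, so no coordinates are printed. The deposited values were used as they stood, without further normalization. After RMA the arrays share nearly 1 distribution: their median log2 values lay between 7.31 and 7.37. A general change in the amount of RNA per sample cannot be seen in such values.

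The deposited table held 36685 probe sets, of which 190 Affymetrix controls were set aside and 36495 were tested. GEO's platform annotation, with symbols brought up to date through the NCBI RefSeq gene table of the GRCr8 assembly, gave 1 gene for 18511 of these probe sets, several genes for 575 and no name for 17409. Those without a name here were tested but not named, and no gene was named from a probe set with several. Each of the 18166 genes was represented by the probe set, naming that gene alone, with the highest mean over all 6 arrays. Fold values are 2 to the power of the difference between the group means of log2 values, and RMA understates differences of genes near background and of very bright genes. The number of arrays limits the precision.

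SAH and sham arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided, no covariate), with Benjamini-Hochberg adjustment over all 36495 probe sets. A gene was called when its adjusted p was under 0.05. Values are given as mean ± SD over 3 arrays, or as a log2 difference, SAH minus sham, with limma's standard error (SE). 36 gene lists, made up of pathway lists and cell type marker lists, were fixed before the data were examined. They named 597 genes, of which 532 were measured here. Each list was tested with limma's camera, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 36 lists. The correlation estimated from the data and limma's fry test were run beside it. The median difference over the members of a list carries a 95% interval from 10000 bootstrap draws of its members. This interval treats genes as if they were independent, which they are not.

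The rule for naming genes was also fixed beforehand. It took up to 12 called genes in each direction with the largest difference and groups that did not overlap, up to 4 members of each list with the smallest p, and a panel of vascular and inflammatory genes. Of this panel Ednra, Ednrb and Acta2 were not measured here by a probe set naming that gene alone. Genes named outside the rule are said to have been chosen after their values were seen.

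The alternatives tried were a filter on dim probe sets (above the array's own median on at least 3 arrays), quantile normalization repeated, array medians subtracted, eBayes with trend and robust options, array weights, an adjusted p under 0.10, an added minimum log2 difference of 1, each array left out in turn, other ways to represent a gene, and list tests without genes shared between lists. A fit with each array's mean over the neutrophil marker list as a covariate was added after the data were seen. With this covariate the lists were tested by camera at the preset correlation only, without the estimated correlation or fry. The groups share no array numbers, so no pairing was modelled.

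Technical differences were looked for in the spike-in hybridisation and labelling controls and in the background probe sets, with exact permutation tests of the group means. A planned check of RNA degradation from control probe sets of Gapdh and Actb could not be made, since no such controls were found among the control probe sets used here.

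The test was checked on simulated data for 3 against 3 arrays, with the real means of the 36495 probe sets and their spreads as moderated by eBayes. Moderated spreads vary less between probe sets than the raw ones, and the effect of this on recovery was not tested. In 10 simulated runs, each with 200 changed probe sets, 3.0% of changes of 0.5 log2 units, 71.2% of changes of 1, 97.4% of changes of 2 and 99.8% of changes of 3 were recovered, and on average 5.30% of the calls were false. A list with a simulated shift was called in 20 of 20 runs, and 2 of 720 unshifted lists were called. The simulation took over means and moderated spreads, not the correlation between genes. In the real data that correlation was estimated between -0.07 for the pericyte list and 0.69 for the NF-kappaB list. The 2 of 720 therefore give no rate of false list calls for the real arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.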

Results

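The arteries of rats 6 hours after SAH, a bleed into the fluid space around the brain, were compared with the arteries of sham-operated rats, with 3 arrays in each group. Each array gave log2 values for 36495 probe sets. Across probe sets, which are not independent replicates, the arrays correlated with r between 0.970 and 0.991. The main direction of spread, the leading principal component, held 44.3% of the variance and placed the sham arrays 6, 7 and 8 at -38.31, -29.73 and -17.04 and the SAH arrays 1, 4 and 5 at -1.06, 32.68 and 53.46. The next component held 18.0% and set sham array 8, at -40.25, apart from the other 5 arrays, the lowest of which lay at -7.18. SAH array 1 correlated with sham array 6 at 0.987 and with SAH array 4 at 0.984. For 7 spike-in and background measures an exact two-sided permutation test of the group means gave p between 0.2 and 0.9, in a design where the smallest possible p is 0.1. The labelling controls varied among the SAH arrays, which a test of group means does not show. The thr control read 7.38, 8.20 and 8.40 in SAH arrays 1, 4 and 5, and 7.72, 7.82 and 7.77 in sham arrays 6, 7 and 8. The dap, phe and lys controls were likewise higher in SAH arrays 4 and 5 than in any sham array.

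The comparison addresses which transcripts of the arterial wall and its surroundings differ 6 hours after the bleed. Genes known to be induced by interferons were among the largest rises. Cxcl9, a chemokine induced by interferon gamma (probe set 17688717), rose 14.9-fold, from 8.14 ± 0.27 in sham to 12.04 ± 0.81 in SAH arteries (mean log2 value ± SD, n = 3 each; limma adjusted p = 0.0106). Rsad2, which encodes the antiviral enzyme viperin (probe set 17821293), rose 12.2-fold, from 9.04 ± 0.19 to 12.65 ± 0.35 (n = 3 each; limma adjusted p = 0.00189). The largest fall was that of Cemip, a gene for a hyaluronan-degrading protein (probe set 17634637), which was 4.98-fold lower, at 9.63 ± 0.26 against 11.95 ± 0.42 (n = 3 each; limma adjusted p = 0.0116). Slc2a4, the insulin-responsive glucose transporter GLUT4, was 2.69-fold lower, at 7.75 ± 0.16 against 9.17 ± 0.10 (n = 3 each; limma adjusted p = 0.00551).

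The 12 largest rises also held Ifgga4l, of the interferon-inducible GTPases, at 11.2-fold, the guanylate-binding protein genes Gbp6 (11.0-fold), Gbp1 (10.2-fold) and Gbp4 (6.75-fold), and Zbp1, a sensor of Z-form nucleic acids, at 10.4-fold. Cmpk2, a mitochondrial nucleotide kinase, rose 9.96-fold, and the antiviral genes Mx1, Isg15, Oasl and Dhx58 rose 9.58-fold, 9.41-fold, 7.88-fold and 6.24-fold. SE of these log2 differences ran from 0.15 for Cmpk2 to 0.52 for Gbp6. The 12 largest falls held the sterol transporter gene Abcg4 (2.94-fold lower), the receptor genes Mas1l (2.78-fold) and Galr2, for galanin (2.47-fold), and Rrad, a small GTPase that restrains calcium channels (2.73-fold). A probe set for the microRNA gene Mir27b was 2.57-fold lower, Efhd1, a mitochondrial calcium-binding protein gene, 2.39-fold, the transcriptional repressor gene Nacc2 2.30-fold, and the laminin chain gene Lama1 2.24-fold. Ppp1r14a, which encodes CPI-17, an inhibitor of myosin phosphatase, and Smtn, which encodes the contractile protein smoothelin, were each 2.27-fold lower.

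**Figure D1:**
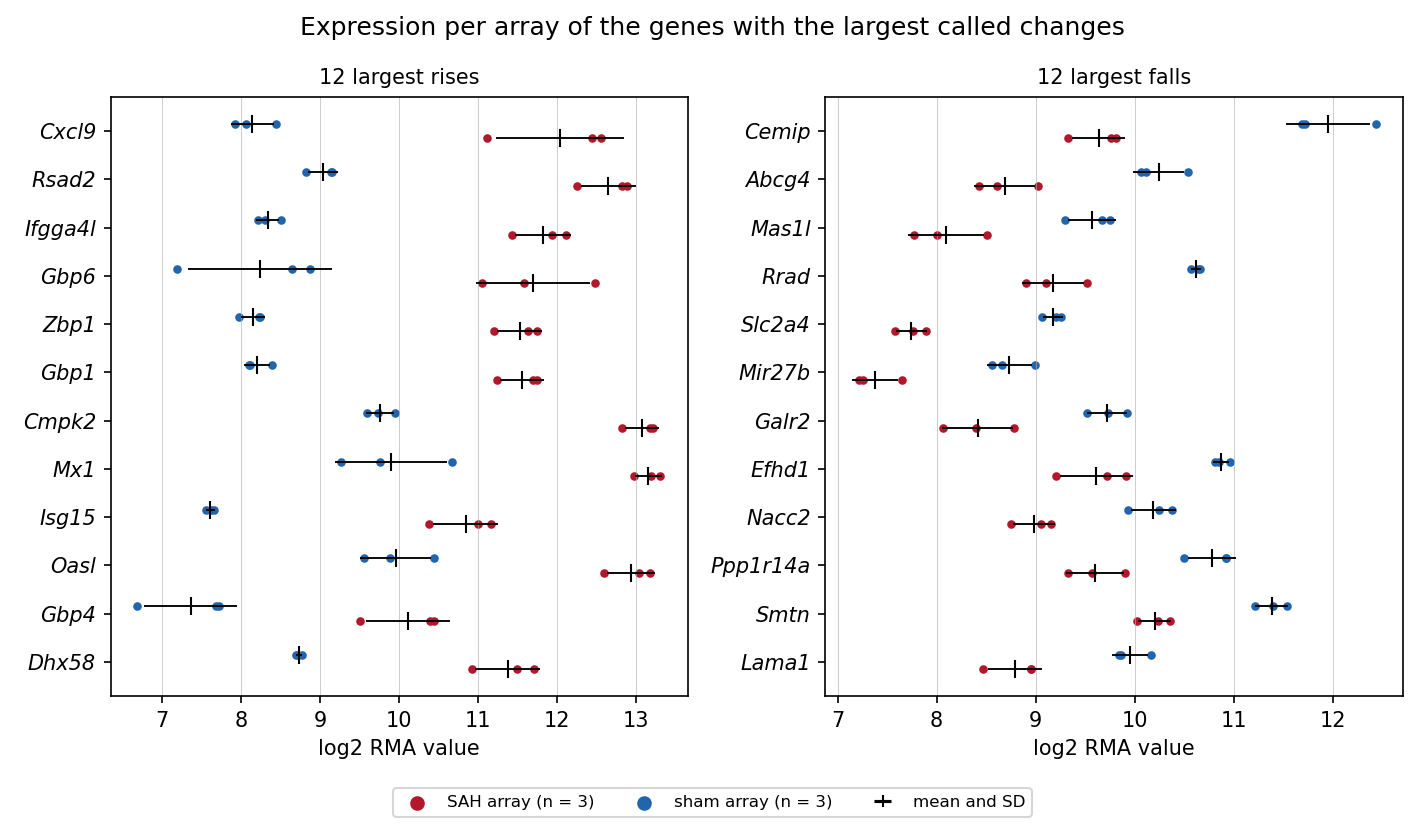
Log2 RMA values (horizontal axes) of the 12 called genes with the largest rises (left) and the 12 with the largest falls (right), with a point for each array, red for SAH and blue for sham, and a black mark and bar for the mean and SD of 3 arrays. The groups do not overlap for any of these genes, and the distance between the means is widest for Cxcl9 (3.89) among the rises and for Cemip (-2.32) among the falls.

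In all, 235 of 18166 genes passed the threshold, 175 of them higher and 60 lower after SAH, and 135 of the rises and 20 of the falls were at least 2-fold. The SAH and sham values of all 235 did not overlap. Over all probe sets, 20.6% did not overlap, where chance gives 10%. Of the 295 probe sets called, 222 were higher and 73 lower, and 49 of them were unnamed here. Leaving out an array moved the count of genes from 235 to 670 without SAH array 1, 41 without SAH array 4, 59 without SAH array 5, 29 without sham array 6, 55 without sham array 7 and 95 without sham array 8. All 235 genes kept their direction in these fits, as they must where the groups do not overlap. With the neutrophil marker mean as a covariate, chosen after the data were seen, 23 genes passed, 22 of them among the 235.

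**Figure D2:**
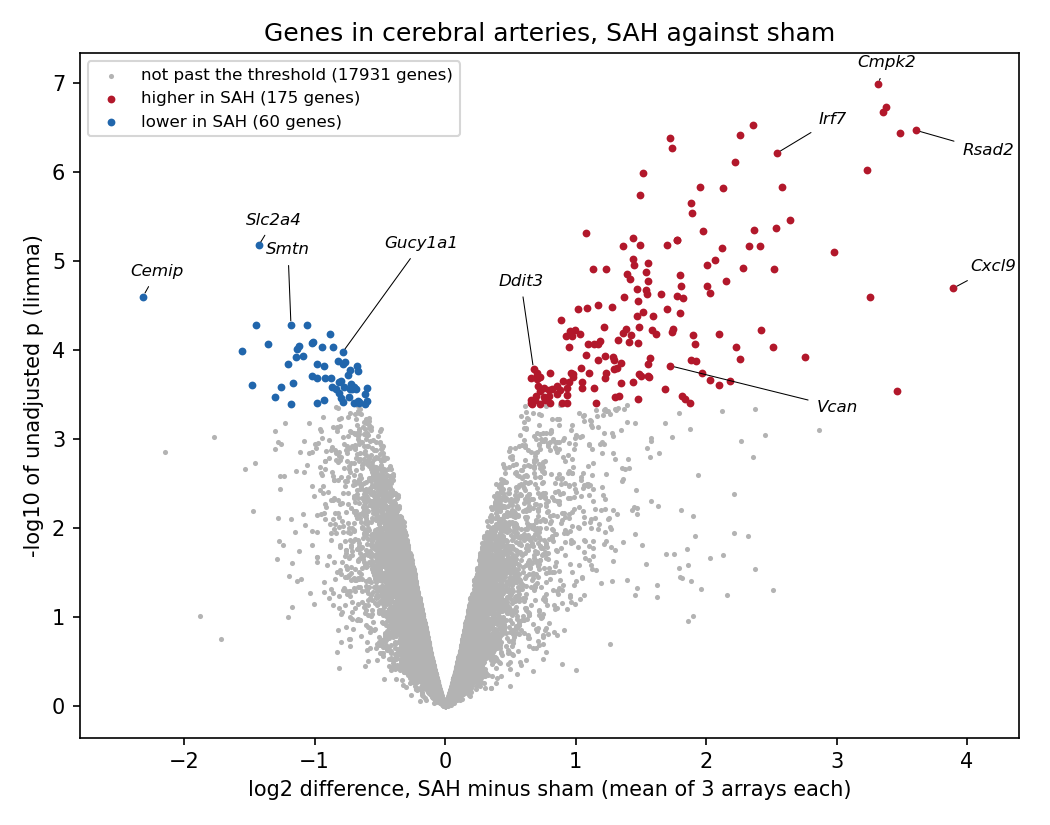
Each point is a gene (18166 in all), with the log2 difference between the means of 3 SAH and 3 sham arrays on the horizontal axis and -log10 of limma's unadjusted p on the vertical axis. The 175 genes higher in SAH (red) reach to 3.89 with Cxcl9, and the 60 genes lower in SAH (blue) to -2.32 with Cemip.

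Genes of the interferon response rose together. Of 21 measured members of the list, 16 rose, none fell and 5 did not pass, and adjusted over the list alone 19 rose. With an array left out, the members past the threshold numbered 19 without SAH array 1, 9 without SAH array 4, 10 without SAH array 5, 8 without sham array 6, 11 without sham array 7 and 13 without sham array 8, with medians of 1.99 to 2.23, and 7 passed with the neutrophil covariate (median 1.82). Rig1, a cytosolic RNA sensor long known as Ddx58, rose 5.12-fold, from 10.17 ± 0.11 to 12.53 ± 0.17, and Irf7, a transcription factor that drives type I interferon genes, rose 5.83-fold, from 9.96 ± 0.09 to 12.51 ± 0.26 (n = 3 each; limma adjusted p = 0.00189 and 0.00221). The median difference over the list was 2.13 (95% interval 1.41 to 2.37), and all 21 differences were above 0. By array, the median of the members stood 1.62, 2.19 and 2.26 above the sham mean in SAH arrays 1, 4 and 5, and at -0.14, 0.05 and 0.04 in sham arrays 6, 7 and 8. The list was called up by camera (adjusted p = 8.73e-30) and by fry (adjusted p = 0.00917), but not with an estimated correlation (adjusted p = 0.798 with an estimated correlation). The guanylate-binding protein, Ifgga and Oas families hold near-identical members, so the share of each member in its family's signal is uncertain.

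**Figure D3:**
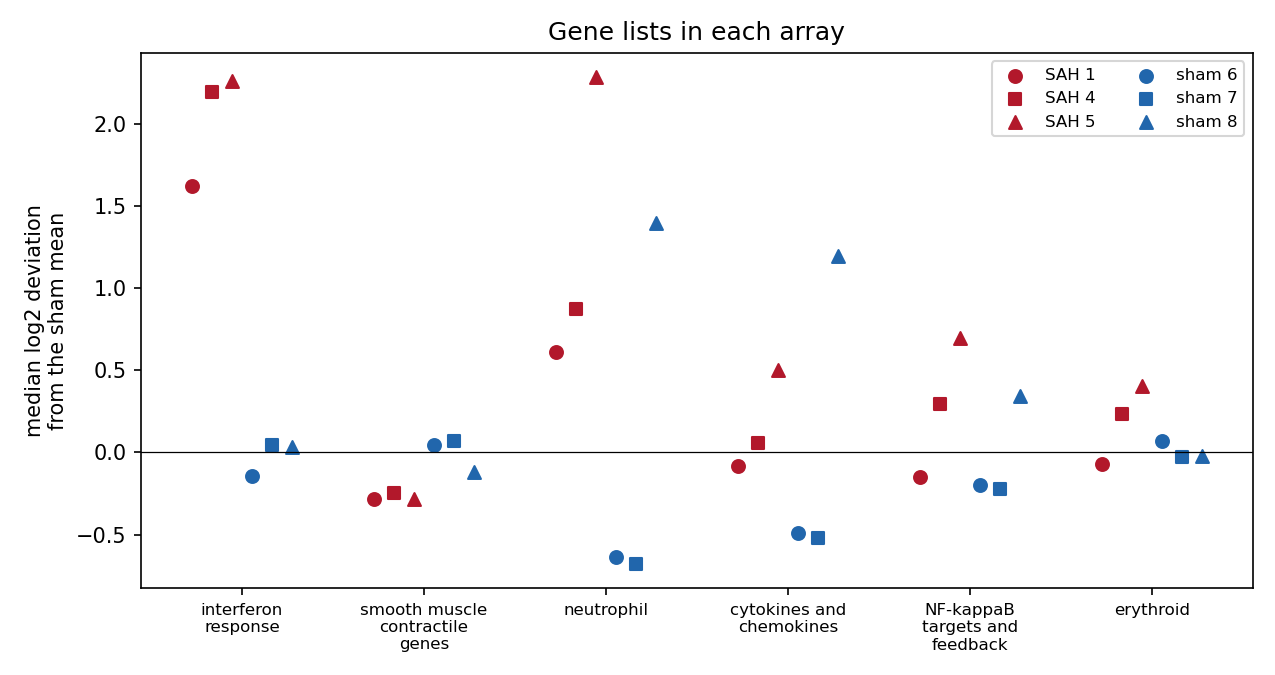
Median over the measured members of 6 gene lists of the log2 deviation from the sham mean (vertical axis) in each array, red for SAH and blue for sham, with a symbol for each array. The SAH arrays lie at 1.62 or above for the interferon list, where no sham array exceeds 0.05, whereas sham array 8 reaches 1.40 for the neutrophil list and 1.20 for the cytokine list.

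Of 18 measured genes of the smooth muscle contractile apparatus 3 fell, none rose and 15 did not pass. Smtn fell from 11.38 ± 0.17 to 10.20 ± 0.17, Pln, which encodes the calcium pump inhibitor phospholamban, from 12.04 ± 0.12 to 11.25 ± 0.12, and Ppp1r14a from 10.78 ± 0.24 to 9.60 ± 0.29 (n = 3 each; limma adjusted p = 0.0197, 0.0390 and 0.0496). Adjusted over the list alone 6 fell. The tropomyosin gene Tpm1 differed by -0.44 ± 0.12 (SE) and Myh11, smooth muscle myosin heavy chain, by -0.40 ± 0.11, with adjusted p of 0.169 and 0.174. The list's median was -0.28 (95% interval -0.42 to -0.20), and 17 of the 18 differences were below 0. It was called down by camera (adjusted p = 8.96e-07), but not with an estimated correlation (adjusted p = 0.879 with an estimated correlation) or by fry (adjusted p = 0.0594). The call of Ppp1r14a ended when quantile normalization was repeated (adjusted p = 0.0544) or array medians were subtracted (0.0517), with differences of -1.18 and -1.19 in these fits. None of the 18 passed without SAH array 4, SAH array 5, sham array 6 or sham array 7, Smtn alone passed without sham array 8 (adjusted p = 0.0425), and all 3 passed without SAH array 1. With the neutrophil covariate none passed either, where Smtn, Pln and Ppp1r14a differed by -0.998 ± 0.134 (SE), -0.65 ± 0.12 and -0.89 ± 0.16, against -1.18 ± 0.13, -0.79 ± 0.11 and -1.18 ± 0.19 without it.

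In the nitric oxide and prostanoid list 2 of 21 genes fell and none rose. Gucy1a1, a subunit of the nitric oxide receptor guanylate cyclase, was 1.72-fold lower (8.09 ± 0.04 against 8.88 ± 0.11, adjusted p = 0.0271), and Ddah2, which breaks down inhibitors of nitric oxide synthase, was 1.58-fold lower (8.66 ± 0.06 against 9.32 ± 0.12, adjusted p = 0.0496, with n = 3 each and limma's test for both). Ddah2 lost its call when quantile normalization was repeated (0.0544) or array medians were subtracted (0.0515), with differences of -0.65 and -0.67 against -0.66. Adjusted over the list alone 6 genes fell and 1 rose. The other guanylate cyclase subunit, Gucy1b1, differed by -0.67 ± 0.13 (SE), Pde3a by -0.81 ± 0.16, and Nos3, endothelial nitric oxide synthase, by -0.39 ± 0.11, with adjusted p of 0.0877, 0.0864 and 0.189. The list was not called (camera, direction down, adjusted p = 0.465), with a median of -0.02 and a mean of 0.05, and was called down with the neutrophil covariate (median -0.16; adjusted p = 0.0293).

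No member of the list of vasoconstrictor receptors and ligands passed among 25 measured, over all genes or adjusted over the list alone, and the list's median was -0.03 (95% interval -0.19 to 0.09; camera adjusted p = 0.753). Edn1, the endothelin precursor gene, differed by 0.67 ± 0.25 (SE) and the serotonin receptor gene Htr1b by 0.44 ± 0.18, with limma adjusted p of 0.287 and 0.339. The values were -0.51 ± 0.20 for the angiotensin receptor gene Agtr1a, 0.05 ± 0.16 for the thromboxane receptor gene Tbxa2r, -0.61 ± 0.18 for Adra1b and -0.42 ± 0.13 for Htr2a, none past the threshold. None of 24 genes for arterial ion channels and calcium handling passed over all genes, while 6 fell and 1 rose adjusted over the list alone. Among them the potassium channel subunit gene Abcc9 differed by -1.08 ± 0.23, the calcium pump gene Atp2a2 by -0.52 ± 0.13 and the cation channel gene Trpc6 by 0.88 ± 0.21, and the list was not called (median -0.11; camera adjusted p = 0.262).

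In the list of cytokines and chemokines, which does not hold Cxcl9, the interferon-inducible chemokine Cxcl10 rose 2.06-fold, from 12.60 ± 0.24 to 13.64 ± 0.10 (n = 3 each; limma adjusted p = 0.0342), and the other 24 measured members of this list did not pass. Il6 differed by 0.90 ± 0.87 (SE), Il1b by 0.35 ± 0.66, Tnf by -0.30 ± 0.55, and Ccl2 stood at 12.72 in both groups. Il6 and Il1b varied within both groups: in sham arrays 6, 7 and 8 Il6 read 9.34, 9.71 and 12.38 and Il1b 9.21, 8.71 and 10.69, and in SAH arrays 1, 4 and 5 Il6 read 10.26, 11.46 and 12.40 and Il1b 9.09, 9.44 and 11.13. The cytokine list was not called (median 0.23; 2 members rose adjusted over the list alone; camera adjusted p = 0.166), but it was called up without sham array 8 (adjusted p = 1.97e-07) and with array weights (0.0290), and called down with the neutrophil covariate (median -0.31; adjusted p = 0.00465). The leukocyte adhesion list was not called either (median 0.44; camera adjusted p = 0.653), with none of 15 genes past the threshold and 3 up and 3 down adjusted over the list alone. There Itgal differed by 0.64 ± 0.13, Jam3 by -0.42 ± 0.09 and Icam1 by -0.16 ± 0.15.

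The lists of NF-kappaB targets (17 measured) and of IL-6 family signalling (18 measured) were called up by camera (adjusted p = 0.0201 for each), but not with an estimated correlation (adjusted p = 0.879 with an estimated correlation for each) or by fry (0.610 and 0.505). No member passed over all genes, 3 of each rose adjusted over the list alone, and the medians were 0.26 and 0.25. Sod2, mitochondrial superoxide dismutase, differed by 0.60 ± 0.10 (SE) with an adjusted p of 0.0630, Cflar by 1.09 ± 0.25, Lifr by 0.68 ± 0.14 and Socs1 by 1.90 ± 0.51. With the neutrophil covariate neither list was called (adjusted p = 0.800 for each) and the medians were -0.04 and -0.08. The calls also ended without SAH array 5 (0.126 and 0.0741), without sham array 6 (0.0993 for each) and without sham array 7 (0.117 and 0.0968).

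Neutrophil markers varied widely within both groups. None of 13 measured passed, over all genes or adjusted over the list alone, and the list had a median of 1.27 (95% interval 0.20 to 1.79). By array the median of the members stood 0.61, 0.87 and 2.28 above the sham mean in SAH arrays 1, 4 and 5, and at -0.64, -0.68 and 1.40 in sham arrays 6, 7 and 8. Trem1 differed by 1.79 ± 0.65 (SE) and Csf3r, the G-CSF receptor gene, by 1.81 ± 0.70. The list was called up by camera (adjusted p = 0.0436), but not with an estimated correlation (adjusted p = 0.879 with an estimated correlation) or by fry (0.610). The call ended without SAH array 1 (0.0551), SAH array 5 (0.239), sham array 6 (0.0996) or sham array 7 (0.167), and without sham array 8 its adjusted p was 7.31e-06. It also ended without genes shared between lists (camera adjusted p = 0.0756).

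Lists of other blood cell markers had smaller medians. T and B lymphocyte markers had no called member among 12, over all genes or adjusted over the list alone, and a median of 0.14, with Cd3e at 0.38 ± 0.14 (SE) and Lck at 0.35 ± 0.12. The list was called up (camera adjusted p = 0.0396), but not with an estimated correlation (adjusted p = 0.879 with an estimated correlation), by fry (0.505), with the filter on dim probe sets (0.196), without SAH array 1 (0.161) or without sham array 7 (0.315). None of 18 monocyte and macrophage markers passed over all genes, whereas 4 rose and 6 fell adjusted over the list alone, with Ptprc at 0.93 ± 0.27 and Csf1r at -0.50 ± 0.11 (median 0.21; camera adjusted p = 0.653). The haemoglobin genes Hbb-b1 and Hba-a1 differed by 0.26 ± 0.23 and 0.34 ± 0.20. The erythroid list (6 measured; median 0.19; camera adjusted p = 0.330) and the platelet list (8 measured; median 0.10; camera adjusted p = 0.236) were not called and had no member past the threshold over all genes or adjusted over the list alone.

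In the endoplasmic reticulum stress list, Ddit3, the transcription factor CHOP, rose 1.60-fold (9.52 ± 0.07 against 8.84 ± 0.04, adjusted p = 0.0342) and Asns, asparagine synthetase, 1.58-fold (10.96 ± 0.10 against 10.31 ± 0.08, adjusted p = 0.0478, with n = 3 each and limma's test for both). These were 2 of 17 measured members, 4 rose adjusted over the list alone, and the list was not called (median 0.06; camera adjusted p = 0.196). Asns lost its call when quantile normalization was repeated (0.0504) or array medians were subtracted (0.0535), with differences of 0.65 in both against 0.66. Trib3 differed by 1.05 ± 0.19 (SE) with an adjusted p of 0.0739. In the structural matrix list Vcan, which encodes the proteoglycan versican, rose 3.31-fold (11.26 ± 0.35 against 9.53 ± 0.35, n = 3 each, limma adjusted p = 0.0326). It was the only one of 18 to pass, over all genes and adjusted over the list alone, and this list was not called (median 0.05; camera adjusted p = 0.231).

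None of 20 genes for matrix proteases and their inhibitors passed, with Mmp13 at 2.03 ± 0.69 (SE), Mmp9 at 0.02 ± 0.77 and Timp1 at 0.25 ± 0.10 (median 0.16; camera adjusted p = 0.376). Coagulation and fibrinolysis genes (15 measured, none called) had a median of 0.18, with Procr at 1.47 ± 0.39 and F13a1 at -0.87 ± 0.21 (camera adjusted p = 0.419). Of 24 genes for haem, iron and antioxidant defence none passed. Hmox1, the haem-degrading enzyme, differed by -0.51 ± 0.33 and Hpx, the haem carrier haemopexin, by 0.90 ± 0.24 (median -0.08; camera adjusted p = 0.516). Hypoxia and glycolysis genes (17 measured, none called, 1 up adjusted over the list alone) included Pfkp at 1.58 ± 0.29 and Vegfa at 0.57 ± 0.18 (median -0.00, mean 0.16; camera, direction up, adjusted p = 0.665). The lists for immediate early genes (25 measured; median 0.13; Fos -1.04 ± 0.45), ERK feedback (20 measured; median 0.02; Spred1 0.47 ± 0.12), heat shock proteins (12 measured; median -0.04; Hspe1 -0.46 ± 0.12), glucocorticoid response and clock (17 measured; median 0.22; Per1 1.00 ± 0.39) and cell cycle (20 measured; median -0.01; Tyms -0.35 ± 0.14) had no called member and camera adjusted p of 0.516, 0.471, 0.618, 0.181 and 0.815. The cell cycle list's mean was 0.02, and camera's direction for it was up. With the neutrophil covariate, tested by camera at the preset correlation alone, the immediate early and ERK feedback lists were called down (camera adjusted p = 3.12e-05 and 0.00415). The glucocorticoid and clock list was called up with it (0.0249). In the lists of this paragraph other than hypoxia and glycolysis no member passed adjusted over the list alone.

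Markers of the other cells of the wall were not called as lists. Medians were -0.22 (95% interval -0.29 to -0.02) for 12 endothelial genes, -0.25 (-0.93 to 0.06) for 8 pericyte genes and -0.19 (-0.42 to -0.08) for 13 fibroblast and leptomeningeal genes, with camera adjusted p of 0.432, 0.103 and 0.0724. No member passed over all genes, and adjusted over the lists alone 1 endothelial gene rose, 3 pericyte genes fell and no fibroblast gene passed. Cdh5, endothelial cadherin, differed by 0.61 ± 0.11 (SE), Cldn5 by -0.76 ± 0.24 and the pericyte and mural cell gene Notch3 by -0.67 ± 0.13.

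Marker lists of tissues next to the arteries had medians on both sides of 0. Oligodendrocyte markers were called up as a list (9 measured, median 0.28, camera adjusted p = 0.0201), but not with an estimated correlation (adjusted p = 0.879 with an estimated correlation), by fry (0.198), with the filter on dim probe sets (0.0642), without SAH array 5 (0.0541) or without sham array 7 (0.0968). No member passed over all genes and 1 rose adjusted over the list alone, with Cnp at 0.88 ± 0.20 (SE) and Mbp, myelin basic protein, at 0.58 ± 0.20. Another probe set of Mbp differed by 0.17 (limma adjusted p = 0.610). Astrocyte markers had a median of -0.38 (8 measured; camera adjusted p = 0.181), with Gfap at -0.59 ± 0.34. The lists for neurons (11 measured, median -0.13), Schwann cells (7, median 0.19), pituitary (8, median 0.02), choroid plexus (7, median -0.11) and skeletal muscle (7, median 0.00) were not called, with camera adjusted p of 0.913, 0.334, 0.653, 0.913 and 0.753, and camera's direction for choroid plexus was up. In these lists and the astrocyte list no member passed over all genes, and adjusted over the list alone only 1 Schwann cell gene rose. The 10 reference genes had a median of -0.05 (camera adjusted p = 0.596), no member past the threshold either way, B2m at 0.27 ± 0.09 and Rpl13a at -0.26 ± 0.09.

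**Figure D4:**
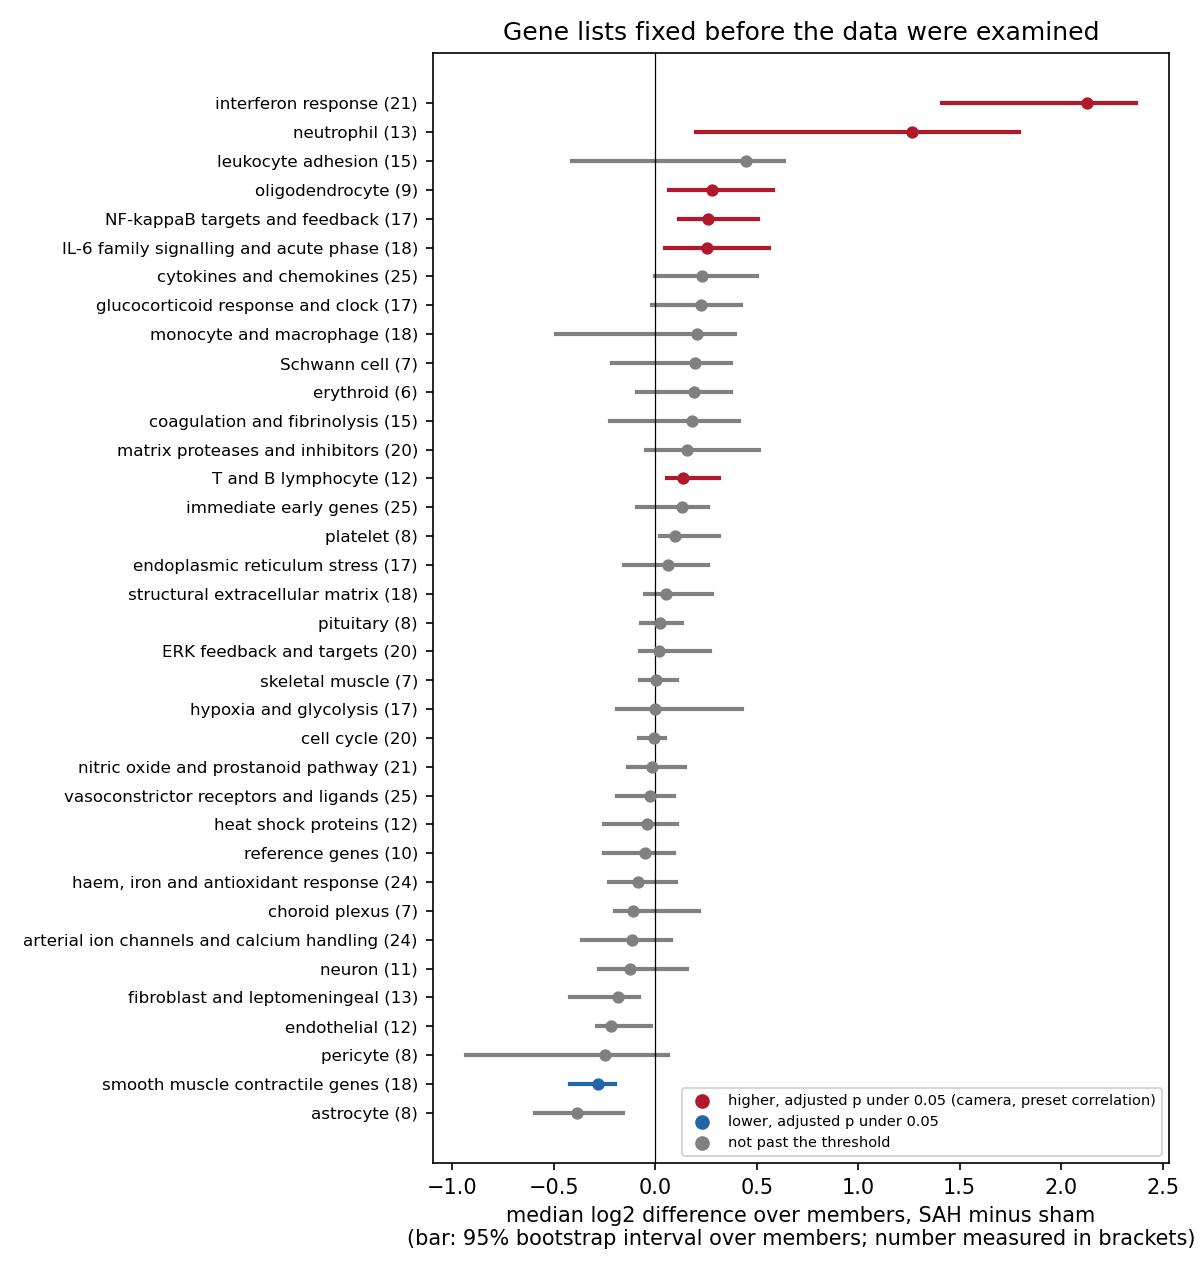
Median log2 difference, SAH minus sham, over the measured members of each of the 36 gene lists (horizontal axis), with bars for the 95% bootstrap interval over members and the number of members in brackets. Lists with a camera adjusted p under 0.05 at the preset correlation are red (6 lists, higher) or blue (1 list, lower), and the interferon list lies farthest from 0 at 2.13.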

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

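The neutrophil covariate was chosen after the data were seen, and lists were tested with it only by camera at the preset correlation. Under all alternatives run, no called gene changed direction, and of the called lists only the NF-kappaB list did, with the neutrophil covariate (camera direction down, adjusted p = 0.800). Leaving out an array could not turn a called gene, as the groups did not overlap. The interferon list stayed past the threshold in all alternatives except the estimated correlation, and the contractile list in all except that and fry. A filter on dim probe sets gave 467 probe sets up and 386 down and 359 genes up and 313 down, with fewer probe sets to adjust over, and it ended the calls of the lymphocyte (adjusted p = 0.196) and oligodendrocyte (0.0642) lists. The trend and robust options gave 145 probe sets and 121 genes down, and array weights 347 probe sets up and 132 down and 266 genes up and 107 down. An adjusted p under 0.10 gave 443 probe sets up and 273 down and 321 genes up and 209 down, and a minimum log2 difference of 1 left 25 probe sets and 20 genes down. The mean of a gene's probe sets, adjusted over 18166 genes, gave 378 genes up and 317 down. With an estimated correlation 0 lists passed camera (1 at an unadjusted p under 0.05, and 1 by fry), with adjusted p of 0.798 for the interferon list and 0.879 for the NF-kappaB, IL-6 family, contractile, neutrophil, lymphocyte and oligodendrocyte lists. By fry 1 list passed, the interferon list, and adjusted p was 0.610 for the NF-kappaB and neutrophil lists, 0.505 for the IL-6 family and lymphocyte lists, 0.0594 for the contractile list and 0.198 for the oligodendrocyte list. Without genes shared between lists the neutrophil list had an adjusted p of 0.0756. The neutrophil covariate, which costs 1 residual degree of freedom, left 30 probe sets up and 0 down and 23 genes up and 0 down in limma, where 1780 probe sets and 1042 genes were lower at an unadjusted p under 0.05. With it 11 lists passed, the calls of the IL-6 family (adjusted p = 0.800) and neutrophil (0.9997, as the source of the covariate) lists ended, and the lists of cytokines, immediate early genes and ERK feedback, not called in the main test, were called down (0.00465, 3.12e-05 and 0.00415), as were those of the nitric oxide pathway (0.0293), neurons (0.0183) and astrocytes (0.0293), while the glucocorticoid and clock list was called up (0.0249). With each array left out in turn, 40 to 689 probe sets were up and 1 to 240 down, and 29 to 487 genes were up and 0 to 183 down, with the lowest of these without sham array 6 (1164 genes lower at an unadjusted p under 0.05) and the highest without SAH array 1. Between 2 and 15 lists passed, the fewest without sham array 7 and the most without sham array 8. Adjusted p in these fits ran from 8.71e-06 to 0.126 for the NF-kappaB list, 1.36e-04 to 0.0993 for the IL-6 family list, 7.31e-06 to 0.239 for the neutrophil list, 0.00240 to 0.315 for the lymphocyte list and 0.00773 to 0.0968 for the oligodendrocyte list. Each of these fits has fewer arrays, which costs calls by construction; beyond that, and for the other settings, the cause was not tested. Quantile normalization repeated and array medians subtracted kept the overall counts of probe sets, genes and lists within 1.5 times, with 225 and 207 of the 235 genes kept. No paired analysis was made because the labels name no pairs. Signal over background limits genes near the floor, and 3 arrays per group recovered 71.2% of simulated changes of 1 log2 unit and 3.0% of those of 0.5.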

Other observations

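The tests of the neutrophil covariate, of the contractile genes, of sham array 8 and of the count of probe sets over splits were chosen after the results were seen, and so were the gene lists and single genes of this paragraph and the next and the genes S100a9, Cxcl2, Sele and Hba-a3 further on. Of 15 genes of antigen presentation by MHC class I, 6 rose and none fell (median 0.96). They included the class I activator Nlrc5 (4.28-fold), the peptide transporter gene Tap1 (2.66-fold), the peptide loading factor gene Tapbp (2.77-fold) and the immunoproteasome gene Psmb9 (2.67-fold). Of 11 genes of the class II pathway, 1 rose, RT1-DMb at 1.69-fold (median 0.34), whereas Cd74 differed by 0.06. Whether the class I and class II lists differ from each other was not tested. The class I genes of the RT1 region resemble one another closely, so rises such as that of RT1-N3 (4.79-fold) or RT1-S3 (2.86-fold) cannot be given to 1 gene with certainty. In a list of necroptosis genes and caspases 4 of 11 rose: Zbp1, the kinase gene Ripk3 (3.25-fold), its substrate Mlkl, the pore-forming effector (3.50-fold), and Casp8 (1.91-fold), while Ripk1 differed by 0.12. Of 16 pattern recognition genes 7 rose, with Tlr3, a receptor for double-stranded RNA, and Ly96, a partner of Tlr4, each 2.71-fold higher. These lists share genes: Tap1, Psmb8 and Psmb9 of the class I list and Rig1 and Ifih1 of the pattern recognition list also belong to the interferon list. Zbp1 counts in both the necroptosis and the pattern recognition list. The rises in these lists are therefore not separate from one another or from that of the interferon list. None of 9 measured interferon genes passed limma's test (median -0.03, with 1 at an unadjusted p under 0.05), with Ifnb1 at -0.08 and Ifng at 0.16. Apart from Ifna4 and Ifnl3, their group means lay below 7.31, the lowest array median. Ifnb1 read 6.05 in SAH and 6.13 in sham, and Ifng 6.64 and 6.48, where background probe sets averaged 5.32 and 5.34. A change this near the floor could be missed, so these values do not show that interferon transcripts were unchanged. The chemokine genes Cxcl11 (2.97-fold), Cxcl17 (5.32-fold) and Ccl22 (4.07-fold) rose as well.

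Of 10 enzymes of serine, glycine, one-carbon and asparagine metabolism 4 rose, namely Psat1 (2.50-fold), Mthfd2 (2.77-fold), Shmt2 (1.63-fold) and Asns, whose call ended when quantile normalization was repeated or array medians were subtracted. All 15 citrate cycle enzymes measured had a difference below 0 (median -0.31), of which only Idh2, mitochondrial isocitrate dehydrogenase, passed, at 1.71-fold lower. Acss1 (1.98-fold), Ech1 (1.72-fold) and Me1 (1.51-fold), enzymes of acetate, fatty acid and malate metabolism, fell too. The calcium channel gene Cacna1d (2.03-fold lower) and the potassium channel gene Kcnh2 (2.13-fold lower) fell as well, while none of the 24 genes in the list of arterial ion channels and calcium handling passed over all genes.

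For the rise of the interferon list (median 2.13), a brightness difference left after normalization is argued against, since the central 95% of 10000 random lists matched on level lay between -0.18 and 0.084 and the reference genes stood at -0.05. Neutrophil content as the whole cause is argued against as well, as far as the marker mean follows it. With each array's neutrophil mean as a covariate the interferon median was 1.82 and 7 of 21 members passed. The list was called at the preset correlation (camera adjusted p = 2.80e-30). The markers are a coarse measure, as 4 of 13 lay above the array median in sham arrays 6 and 7. Newly arrived leukocytes of all kinds cannot be told apart from a response of the arteries: the neutrophil median of 1.27 lay above 1.06, which is 50% of the interferon median, but its interval ran from 0.20 to 1.79, and the monocyte and lymphocyte medians were 0.21 and 0.14 with upper bounds of 0.39 and 0.31, the monocyte members going both ways. In sham array 8 the neutrophil deviation was 1.40, above SAH arrays 1 and 4 (0.61 and 0.87), while its interferon deviation was 0.04. S100a9 read 10.63 in sham array 8, above both of these SAH arrays. Csf3r read 10.45 there, above SAH array 4 (9.94) but below SAH array 1 (10.65). A response to the bleed, in the arteries or in cells within them, may account for the rise.

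For the lower contractile genes, 1 fall shared by all 18 members is argued against. Their differences ran from -1.18 to 0.02 with a spread (Q, weighted by SE) of 103. This lay above 51.9, the upper bound of the central 95% of 10000 draws with 1 shared difference, of which 6 reached the observed Q. A smaller share of smooth muscle RNA would lower all members alike only if other cells in the samples did not express them. That was not tested, so the spread cannot exclude a smaller share as the whole cause. Bright genes are compressed on arrays, but the 9 members dimmest in sham had a Q of 66.5 against an upper bound of 30.3. The 15 members that were not called had a Q of 14.9, below the median of such draws. Leaving out the called members narrows the spread by itself, so this Q cannot decide whether a smaller share accounts for part of the fall. A smaller share of all wall RNA cannot be excluded for the fall of the list's median. The median over all 18 contractile members differed from that of 33 endothelial, pericyte and fibroblast genes by -0.093 (95% interval -0.25 to 0.05). A change in the muscle cells themselves stays open as well and was not tested apart from it.

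Sham array 8 stood out for neutrophil and cytokine genes, whose medians lay 2.09 and 1.80 above the mean of sham arrays 6 and 7. It may have been an SAH sample under a wrong label, but this is argued against, since its interferon median lay 0.054 above those arrays and the lowest SAH array lay 1.5 above them (SD of the 3 SAH arrays 0.45). More blood in the sample cannot be excluded. The haemoglobin genes Hbb-b1, Hba-a3 and Hba-a1 differed by -0.04, 0.12 and 0.42, far less than the neutrophil median, but whether they follow blood here was not tested. Hbb-b1 read 8.83, 9.55 and 9.65 in SAH arrays 1, 4 and 5 against 8.90, 9.30 and 9.06 in sham arrays 6, 7 and 8, with groups that overlap. The erythroid median of -0.036 adds little, as 1 of its 6 genes lay above the array median in sham. Inflammation in that animal, from surgery or otherwise, was not tested and stays open. In this array Cxcl2 read 12.23 and Sele 9.93, against at most 10.29 and 8.09 in any other array.

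The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 295 probe sets and 235 genes, and the highest of the other 9 splits gave 0 of each in limma (163 to 1521 genes at an unadjusted p under 0.05, against 3385 in the real split). For gene lists the real split gave 7 and the highest other 19, and 6 of the 10 splits, the real one included, gave at least 7. The split with 19 set SAH array 1 and sham arrays 6 and 7 against SAH arrays 4 and 5 and sham array 8, which points to a structure of the samples that the groups do not describe: between its sides the neutrophil and cytokine medians differed by 1.64 and 1.16. The interferon median was 2.13 between the real groups and at most 0.89 between the sides of any other split, and the contractile median differed by 0.28 and at most 0.19. Every other split puts arrays of both groups on each side, which by itself shrinks a difference between the groups and costs calls.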
